A study of Homo sapiens with 6 samples.

How the data were processed

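Human pancreatic islets from non-diabetic donors were cultured and given phosphate-buffered saline (PBS), extracellular vesicles (EVs) from MCF-10A cells, a non-tumorigenic breast epithelial line, or EVs from MDA-MB-231 cells, a breast cancer line. EVs are membrane-bound particles that cells release and that carry proteins and RNA. Per the labels, each addition was made 2 times, 24 h apart, and RNA was taken 24 h after the last one. The 6 samples fell into 3 groups of 2, and groups and replicate numbers were taken from the labels. The labels do not say that the replicates came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical.

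Per the labels' protocols, total RNA was treated with DNase and made into libraries with an mRNA kit that used random priming and PCR. The kit is not stated to mark strand. Per the submitters' processing notes, Trim Galore, HISAT2 and the build hg38 were used. Their versions, the tool that counted reads and the gene annotation are not given in the sources used here. The authors deposited whole-number read counts per gene, not normalized, with 1 column per sample. PCR reads without molecular identifiers are not independent molecules, so counting error alone understates the error of a count.

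The table held 58735 features, of which 58708 had names found in GENCODE release 29, the annotation of hg38 used here for coordinates, gene types, lengths and GC content. Length and GC content were those of the longest annotated transcript of a gene, which need not be the one expressed. The other 27 features had date-like names of the kind a spreadsheet makes from gene symbols, and they were kept in the library totals but not named. A further 1745 features repeated 1 of 177 symbols and are not named either. Genes on the Y chromosome and XIST were left out of the tables of results. All 6 columns were used. Totals ran from 14979459 to 18179195 counts per library.

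Genes were tested with edgeR (4.0.16, in R 4.3.3) on the counts as deposited. The steps were filterByExpr on the groups, TMM scaling, a common and trended dispersion, a robust quasi-likelihood fit of all 6 samples and 2-sided quasi-likelihood F tests. Benjamini-Hochberg adjustment was applied over the 19696 genes tested, which held 99.8% of the counts, with a threshold of 0.05. The fit had 3 residual degrees of freedom, a median prior of 16.4 degrees of freedom and a common biological coefficient of variation of 11.0%. TMM factors ran from 0.975 to 1.03. Levels are given as TMM-normalized CPM, the reads of a gene scaled to a common library size,, mean ± SD over the 2 replicates, and changes as log2 fold change ± SE. An exact permutation of 2 against 2 samples cannot go below p = 0.333, so no such test was made.

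Before the data were examined, the groups, tests, alternatives, gene lists and the rule for named genes were fixed. Named genes were, per comparison, the 10 called genes with the largest change in each direction among those with a mean CPM of at least 5, both replicates of one group above both of the other and a symbol that is not a clone name. Where fewer than 5 passed in a direction, the 5 with the smallest p there were taken and are given as not past the threshold. Up to 4 members with the smallest p came from each list, and INS, IAPP, PDX1, MAFA, GCG, SST, PPY, SLC2A2, PKM, CS, PRSS1, KRT19 and COL1A1 were always named. The results of some genes that the rule takes are not reported here. HLA and immunoglobulin genes stayed out of the first part of the rule. Genes outside this rule are said to have been chosen after their values were seen.

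The 30 lists held 708 members, all found in the table, CCN1 and CCN2 under their older names CYR61 and CTGF. They covered beta cell identity, insulin secretion machinery, alpha cells, delta, PP and epsilon cells, acinar, ductal, stellate and fibroblast, endothelial, leukocyte, Schwann and blood cells, and basal epithelial genes of the MCF-10A type. The others were glycolysis, pyruvate and TCA cycle, nuclear-encoded respiratory chain, mitochondrially encoded mRNA, ribosomal proteins, endoplasmic reticulum (ER) stress, heat shock, hypoxia, inflammatory and NF-kB genes, interferon-stimulated genes, immediate early genes, cell cycle, p53 and apoptosis, experimentally reported miR-122 targets, cholesterol biosynthesis, TGF-beta response and matrix, metallothioneins, and beta cell dedifferentiation. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, which compares a list with all other genes, with adjustment over the 29 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. The blood list had 1 tested member and no test.

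The test was checked on simulated counts drawn from the means and library sizes of the real samples, with 200 genes changed. For MDA-MB-231 EV against PBS it called 42.1% of genes changed 1.5-fold, 45.2% of those changed 2-fold and 82.9% of those changed 4-fold, with 10 unchanged genes called among 19070 tested. For MDA-MB-231 EV against MCF-10A EV these were 36.6%, 57.6% and 76.2%, with 7 unchanged genes called among 19021. For MCF-10A EV against PBS they were 42.0%, 75.4% and 79.0%, with 9 among 19062. A simulated list of 30 genes shifted by 0.4 (log2) was called by camera with the preset correlation in each of the 3 comparisons. With an estimated correlation its adjusted p by camera was 0.109, 0.0596 and 0.123 in the order above, so the estimated correlation missed a real shift of this size in these simulations. With the preset, 0 of 28 unshifted lists were called. Genes were drawn independently of each other here. The simulations therefore cannot show how often the preset calls unshifted lists whose members vary together, as members of real lists can.

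Alternatives were median-of-ratios scaling, no filter and a filter at a mean CPM of 5, DESeq2 (1.42.0), limma-voom, a fit of only the 4 samples compared, the replicate number as a block and each library left out in turn. When a library was left out, its group's lone sample was assumed to vary like the other groups. A correction of each library for transcript length and GC content was added after the data were seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes with near-identical copies, such as CTRB1 and CTRB2, REG1A and REG1B, the PRSS and metallothionein families, ribosomal protein genes with many pseudogenes, UGT2B15, VDAC1P8 and PKD1P5, are uncertain, since how reads that fit several copies were counted is not given in the sources used here. Genes overlapped by an antisense gene share this uncertainty because counting is not stated to use strand.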

Results

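Messenger RNA was sequenced from human islets of Langerhans after addition of PBS, MCF-10A EVs or MDA-MB-231 EVs, with 2 libraries per group. The depth was 18179195 and 16461714 counts in PBS replicates 1 and 2, 14979459 and 17419991 in the MCF-10A EV replicates, and 14993537 and 15864670 in the MDA-MB-231 EV replicates. The mRNA of GCG, which encodes glucagon, made up 7.44% of counts in PBS, 6.31% in MCF-10A EV and 7.30% in MDA-MB-231 EV libraries (SD 0.0564, 0.680 and 0.156, n = 2 each). INS, which encodes insulin, made up 0.859% ± 0.233, 0.641% ± 0.0902 and 0.999% ± 0.0241 (SD, n = 2). The ratio of GCG to INS counts ran from 7.08 to 10.7 over the 6 libraries.

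On average, libraries of one group were barely closer to each other than to other groups, and this did not hold for each group. Pearson correlations of log2 CPM across the 19696 tested genes, which are not independent replicates, ran from 0.978 to 0.983 within groups and from 0.977 to 0.981 between them. PBS replicate 2 correlated at 0.978 with PBS replicate 1 and at 0.979 to 0.981 with the EV libraries. MDA-MB-231 EV replicate 1 correlated at 0.979 with its replicate and at 0.980 with MCF-10A EV replicate 2. Counts of the replicates differed by more than sampling noise in each group, with a chi-square per degree of freedom of 12.8 for PBS, 7.10 for MCF-10A EV and 6.51 for MDA-MB-231 EV, so each library was counted as 1 sample. Of the replicate pairs, that of PBS was the most unlike. The first 2 principal components held 23.6% and 21.6% of the variance.

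The comparison of MDA-MB-231 EV with PBS asks what vesicles of a breast cancer line do to islet gene expression, a question tied to reports that such vesicles carry miR-122 and lower insulin secretion. No gene passed the threshold. Among genes with a mean CPM of at least 5, those with the smallest p were PLIN2, a lipid droplet coat protein, at 58.3 ± 5.09 CPM against 37.5 ± 3.50 (log2 fold change 0.64 ± 0.12), and TFF1, a secreted mucosal peptide, at 4.86 ± 0.643 against 17.2 ± 5.84 (-1.82 ± 0.30). FLT1, a VEGF receptor, stood at 1.18 ± 0.25, the cytokine IL1B at 1.26 ± 0.28, AKR1B10 at 0.72 ± 0.15, PLPP1 at 1.02 ± 0.23 and CEACAM6 at -1.03 ± 0.22. SPTBN5 (-0.88), SERPINB2 (-0.97) and the pseudogene VDAC1P8 (-0.92) completed the lower genes. PLIN2 lies on chromosome 9, 19108375 to 19149290 (hg38), TFF1 on chromosome 21, 42362282 to 42366594 and FLT1 on chromosome 13, 28300344 to 28495145, and all 3 are annotated as protein-coding. The adjusted p was 0.235 for PLIN2 and 0.239 for TFF1 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. The threshold was passed without PBS replicate 2 by PLIN2 (0.74), TFF1 (-2.13) and SERPINB2 (-1.31), without MCF-10A EV replicate 1 by PLIN2 (0.64), TFF1 (-1.82) and CEACAM6 (-1.03), without MCF-10A EV replicate 2 by PLIN2 (0.64), TFF1 (-1.82) and CEACAM6 (-1.03), and without MDA-MB-231 EV replicate 2 by IL1B (1.67).

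The 4 islet hormones did not pass the test in this comparison. INS stood at 10213 ± 161 CPM with MDA-MB-231 EV and 8655 ± 2377 with PBS (log2 fold change 0.24 ± 0.16), and GCG at -0.0065 ± 0.13. SST, which encodes somatostatin, was at 0.17 ± 0.12, and PPY, which encodes pancreatic polypeptide, at 0.75 ± 0.71. IAPP was at 0.19 ± 0.39. The beta cell transcription factors PDX1 and MAFA were at 0.076 ± 0.092 and 0.088 ± 0.10, and the glucose transporter SLC2A2 at 0.20 ± 0.14. PKM and CS, both reported miR-122 targets, were at 0.092 ± 0.11 and 0.030 ± 0.089. The acinar protease PRSS1 was at 0.17 ± 0.17, the ductal keratin KRT19 at -0.19 ± 0.13 and the collagen gene COL1A1 at 0.31 ± 0.35. Each of these had an adjusted p of 0.998 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. The miR-122 target list had a median of 0.042 with 11 of 15 members positive (camera, Benjamini-Hochberg adjusted p = 0.179), and among its members GYS1 was at 0.24 ± 0.13 and CCNG1 at 0.13 ± 0.096. Without PBS replicate 2 COL1A1 was past the threshold, at 0.85.

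Endothelial genes were the list with the largest positive shift. Their median was 0.56, 13 of 14 members were positive, 0 were called over all genes and 5 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.05e-09, and adjusted p = 0.557 with an estimated correlation). Examples were CDH5, the adhesion molecule of endothelial junctions (1.23 ± 0.38), ENG (0.60 ± 0.16) and KDR (0.84 ± 0.30), beside FLT1. Levels were low for CDH5 (4.25 CPM with MDA-MB-231 EV against 1.82 with PBS) and KDR (5.91 against 3.31), and higher for ENG (23.1 against 15.3). The mean of the endothelial list also differed between replicates, replicate 2 minus replicate 1 being 0.43 for PBS, -0.47 for MCF-10A EV and 0.33 for MDA-MB-231 EV. Metallothioneins, which bind zinc and copper, had a median of 0.42 (7 of 7 positive, 1 adjusted over the list alone, camera adjusted p = 0.000193, and adjusted p = 0.557 with an estimated correlation). Stellate and fibroblast genes had a median of 0.29 and a mean of 0.15, with SPARC at 0.31 ± 0.10 (0 called over all genes and 0 adjusted over the list alone, camera adjusted p = 2.71e-06, and adjusted p = 0.557 with an estimated correlation). Inflammatory genes had a median of 0.26 with 28 of 32 positive and 1 adjusted over the list alone (camera adjusted p = 2.77e-07, and adjusted p = 0.591 with an estimated correlation). Only the endothelial list stayed called without each of the 6 libraries, and its median then ran from 0.32, without MDA-MB-231 EV replicate 2, to 0.75. The inflammatory median was -0.080 without MDA-MB-231 EV replicate 1, with a test past the threshold in the downward direction, the stellate median 0.094 without PBS replicate 1 and no longer called, and the metallothionein list lost its call without PBS replicate 2 at 0.45. Medians that stayed past the threshold moved by over 1.5 times without PBS replicate 1 for endothelial cell genes (0.36), without PBS replicate 2 for stellate and fibroblast genes (0.50), without MDA-MB-231 EV replicate 1 for metallothionein genes (0.20) and inflammatory genes (-0.080), and without MDA-MB-231 EV replicate 2 for endothelial cell genes (0.32), metallothionein genes (0.25) and inflammatory genes (0.62).

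Smaller positive medians were seen in 10 further lists, and none held with an estimated correlation, from adjusted p = 0.557 with an estimated correlation for hypoxia to 0.641 for TGF-beta response. By median these were acinar 0.20, hypoxia 0.19, immediate early 0.19, leukocyte 0.15, heat shock 0.14, glycolysis 0.13, dedifferentiation 0.12, ribosomal proteins 0.11, respiratory chain 0.11 and TGF-beta response 0.10. Their camera adjusted p ran from 2.75e-10 for ribosomal proteins to 0.00692 for dedifferentiation. Of their members 0 were called over all genes or adjusted over the list alone. Members with the smallest p were SPINK1 (0.33 ± 0.094) and REG1B (0.40 ± 0.12) among acinar genes, CA12 (0.87 ± 0.22) among hypoxia genes, LYZ (0.29 ± 0.10) among leukocyte genes and SLC16A1 (0.61 ± 0.21) among glycolysis genes. Over protein-coding genes with a mean CPM of at least 5, log2 fold changes had a Spearman rho of -0.173 with transcript length and 0.0384 with GC content. The 220 whose longest transcript had at most 1000 bases had a median of 0.13. Genes are not independent replicates. Without PBS replicate 2 the medians were -0.017 for ribosomal proteins, -0.016 for the respiratory chain, 0.070 for acinar and 0.16 for leukocyte genes, none of them called. Without PBS replicate 1 they were 0.032 for glycolysis, 0.056 for hypoxia, 0.085 for immediate early, 0.11 for heat shock, 0.050 for dedifferentiation and -0.14 for TGF-beta genes, none of them called. Acinar genes stood at -0.054 without MDA-MB-231 EV replicate 2, and without replicate 1 TGF-beta genes stood at -0.093, heat shock at 0.077 and dedifferentiation at 0.0097, again without a call. Shifts by over 1.5 times that kept the call were seen without PBS replicate 1 for acinar cell genes (0.34), leukocyte genes (0.33), ribosomal protein genes (0.25) and respiratory chain genes (0.22), without PBS replicate 2 for hypoxia genes (0.33), immediate early genes (0.34), heat shock genes (0.23), dedifferentiation genes (0.35) and TGF-beta response genes (0.52), and without MDA-MB-231 EV replicate 2 for hypoxia genes (0.30), leukocyte genes (0.24), heat shock genes (0.24), dedifferentiation genes (0.23) and TGF-beta response genes (0.32).

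The remaining lists were not called against PBS. Medians were 0.057 for beta cell identity (camera, Benjamini-Hochberg adjusted p = 0.132), 0.028 for insulin secretion machinery (0.373), -0.058 for alpha cells (0.291), 0.027 for delta, PP and epsilon cells (0.322) and -0.068 for ductal cells (0.179). They were -0.13 for Schwann cells (camera adjusted p = 0.663), -0.16 for basal epithelial genes (0.291), 0.012 for pyruvate and TCA cycle (0.652), -0.039 for mitochondrially encoded mRNA (0.397), 0.050 for ER stress (0.0549) and 0.054 for interferon-stimulated genes (0.322). Cell cycle stood at 0.094 (camera adjusted p = 0.231), p53 and apoptosis at 0.063 (0.179) and cholesterol biosynthesis at 0.0081 (0.687). No member of these lists was past the threshold over all genes or adjusted over the list alone. ALAS2, the tested member of the blood list, was at 0.89 ± 0.81. By edgeR quasi-likelihood 0 genes were called, with 923 at an unadjusted p under 0.05 (4.69% of those tested), while DESeq2 called 5 and limma-voom 0. The replicates of the groups did not overlap for 31.5% of genes, where chance gives 33.3%. The count was 42 without PBS replicate 2, 1 without PBS replicate 1, 7 and 6 without MCF-10A EV replicates 1 and 2, and 8 without MDA-MB-231 EV replicate 2.

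Setting MDA-MB-231 EV beside MCF-10A EV compares vesicles of the cancer line with vesicles of a non-tumorigenic line. Of 17 ductal genes, 3 were called lower with MDA-MB-231 EV, and the shift of the list did not hold with an estimated correlation (adjusted p = 0.353 with an estimated correlation). SLC4A4, the sodium bicarbonate cotransporter of duct cells, stood at 104 ± 0.132 CPM against 172 ± 16.4 (log2 fold change -0.73 ± 0.094), the transcription factor ONECUT2 at 32.4 ± 1.35 against 58.9 ± 1.76 (-0.86 ± 0.11) and the annexin ANXA4 at -0.56 ± 0.11. The acinar genes CTRB1, which encodes chymotrypsinogen, and PNLIPRP1, a lipase relative, fell with log2 fold changes of -0.56 ± 0.11 and -0.79 ± 0.16. The chemokine CXCL2 fell with -1.07 ± 0.18 and lysozyme, LYZ, with -0.63 ± 0.10. The adjusted p was 0.00133 for SLC4A4, 0.00133 for ONECUT2, 0.0268 for ANXA4, 0.0210 for CTRB1, 0.0389 for PNLIPRP1, 0.00823 for CXCL2 and 0.00619 for LYZ by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. SLC4A4 lies on chromosome 4, 71062667 to 71572087 (hg38) and ONECUT2 on chromosome 18, 57435685 to 57491297. Calls were lost without MCF-10A EV replicate 1 for ANXA4 (-0.57), without MCF-10A EV replicate 2 for ANXA4 (-0.55), CTRB1 (-0.51), PNLIPRP1 (-0.71) and LYZ (-0.53), without MDA-MB-231 EV replicate 1 for CTRB1 (-0.44) and PNLIPRP1 (-0.52), and without MDA-MB-231 EV replicate 2 for ANXA4 (-0.45) and CXCL2 (-0.85).

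In all, 102 genes were called, 8 higher and 94 lower with MDA-MB-231 EV. This split depended on the setting. Of the calls 7.84% were higher, against 5.94% with a mean CPM of at least 5, 9.17% with limma-voom, 12.8% with the replicate block and 14.4% with DESeq2. The share was 29.4% with no filter on low counts, 33.8% with only the 4 samples compared and 56.0% after the length and GC correction. Among called genes with a mean CPM of at least 5 over the 6 libraries, the 10 largest falls were EPN3 (-1.55 ± 0.27), C6orf141 (-1.46), the long non-coding RNA UCA1 (-1.42), BARX2 (-1.37), CEACAM6 (-1.35 ± 0.21), HSD17B2 (-1.31), the transcription factor GATA4 (-1.30), EVPL (-1.19), EPS8L1 (-1.19) and PAQR5 (-1.15). Their adjusted p ran from 0.00823 for EPS8L1 to 0.0389 for GATA4 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Among the 8 genes that rose were the glucose transporter SLC2A3 (0.79 ± 0.17), the phosphodiesterase PDE10A (0.63 ± 0.10), UBL5 (0.62), PYURF (0.52), RPL36AL (0.45) and C9orf3 (0.44). PDE10A had an adjusted p of 0.00619 and RPL36AL of 0.0497 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. CD44 fell with a log2 fold change of -0.46 ± 0.097 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0343). Of the 26 called genes the rule named, SLC4A4, ONECUT2 and EPS8L1 stayed called without each of the 6 libraries. Calls were lost without MCF-10A EV replicate 1 for EPN3 (-1.32), PDE10A (0.53) and CD44 (-0.49), without MCF-10A EV replicate 2 for UCA1 (-1.30), CEACAM6 (-0.92) and CD44 (-0.42), without MDA-MB-231 EV replicate 1 for EPN3 (-1.38) and CEACAM6 (-1.30), and without MDA-MB-231 EV replicate 2 for CEACAM6 (-1.40) and CD44 (-0.34). The other called genes of this paragraph also lost their call without at least 1 of these libraries and kept their sign.

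Ductal genes had a median of -0.56, with 16 of 17 negative, 3 called over all genes and 12 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.05e-22, and adjusted p = 0.353 with an estimated correlation). Acinar genes had a median of -0.41, with 25 of 27 negative, 2 called and 6 adjusted over the list alone (camera adjusted p = 2.91e-11, and adjusted p = 0.421 with an estimated correlation). Inflammatory genes had a median of -0.38, with 26 of 32 negative, CXCL2 called and 3 adjusted over the list alone (camera adjusted p = 4.92e-12, and adjusted p = 0.427 with an estimated correlation). TSPAN8, a further ductal gene, was at -0.78 ± 0.16 and TNFAIP2, an inflammatory gene, at -1.22 ± 0.24, neither past the threshold. PRSS1 stood at -0.47 ± 0.17, KRT19 at -0.46 ± 0.13 and REG1A at -0.41 ± 0.11, likewise not past it. Without MDA-MB-231 EV replicate 2 the inflammatory median was -0.13 and not called. Still called, medians moved by over 1.5 times without MCF-10A EV replicate 2 for acinar cell genes (-0.26), without MDA-MB-231 EV replicate 1 for acinar cell genes (-0.26) and inflammatory genes (-0.84), and without MDA-MB-231 EV replicate 2 for ductal cell genes (-0.28) and acinar cell genes (-0.68). The threshold was passed without MDA-MB-231 EV replicate 1 by KRT19 (-0.67), and without MDA-MB-231 EV replicate 2 by PRSS1 (-0.72).

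Beta cell identity genes had a median of 0.18, with 23 of 24 positive, 0 called over all genes and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.70e-07, and adjusted p = 0.353 with an estimated correlation). INS stood at 10213 ± 161 CPM with MDA-MB-231 EV and 6281 ± 913 with MCF-10A EV (log2 fold change 0.70 ± 0.16) and NPTX2 at 0.39 ± 0.10, with adjusted p of 0.0896 and 0.0948 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. INS was past the threshold without PBS replicate 1 (0.70), PBS replicate 2 (0.70) and MCF-10A EV replicate 1 (0.86), with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.000160, 0.000282 and 0.0436. PBS libraries enter this comparison only through the shared estimate of spread, and the PBS replicates differed in INS (SD 2377 CPM). Delta, PP and epsilon cell genes had a median of 0.26 with 1 adjusted over the list alone (camera adjusted p = 0.000605, and adjusted p = 0.353 with an estimated correlation). SST stood at 0.26 ± 0.12 and PPY at 1.14 ± 0.73. Insulin secretion machinery had a median of 0.065 with 2 adjusted over the list alone (camera adjusted p = 0.00580, and adjusted p = 0.642 with an estimated correlation). Its call was lost without MCF-10A EV replicate 2, at 0.033, and without MDA-MB-231 EV replicate 2, at 0.017. GCG was at 0.27 ± 0.13, IAPP at 0.53 ± 0.39, PDX1 at 0.082 ± 0.093, MAFA at 0.12 ± 0.10, SLC2A2 at 0.25 ± 0.14, PKM at 0.047 ± 0.11 and CS at -0.067 ± 0.089, and none passed the test. COL1A1 had no stable direction here, as a correction for length and GC content put it at 0.23, from -0.0044. CS was at 0.0012 after that correction, which also moved the median of all genes to 0.063. Without each library in turn CS stayed negative, from -0.10 to -0.027. Called medians moved by over 1.5 times without MCF-10A EV replicate 1 for insulin secretion genes (0.12), without MDA-MB-231 EV replicate 1 for insulin secretion genes (0.15), and without MDA-MB-231 EV replicate 2 for beta cell identity genes (0.11).

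Ribosomal protein genes were higher with MDA-MB-231 EV in 78 of 78 cases, with a median of 0.28, 0 called over all genes and 45 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.79e-33, and adjusted p = 0.427 with an estimated correlation). RPLP1 was at 0.43 ± 0.11. The mean of the ribosomal list also differed between replicates, replicate 2 minus replicate 1 being -0.28 for PBS, -0.12 for MCF-10A EV and -0.083 for MDA-MB-231 EV. Its members moved together and do not count as independent results. Respiratory chain genes had a median of 0.21, 66 of 72 positive and 10 adjusted over the list alone (camera adjusted p = 7.96e-15, and adjusted p = 0.466 with an estimated correlation), with NDUFB2 at 0.49 ± 0.12. Metallothioneins had a median of 0.59 and 6 of 7 adjusted over the list alone (camera adjusted p = 3.04e-07, and adjusted p = 0.353 with an estimated correlation), with MT2A at 0.80 ± 0.25. Endothelial genes had a median of 0.55, 14 of 14 positive and 4 adjusted over the list alone (camera adjusted p = 3.52e-05, and adjusted p = 0.466 with an estimated correlation). The endothelial call was lost without MDA-MB-231 EV replicate 2, at 0.30. The endothelial median was 1.00 without MCF-10A EV replicate 1 and 0.20 without replicate 2, still called. Across protein-coding genes with a mean CPM of at least 5, log2 fold changes in this comparison had a Spearman rho of -0.150 with transcript length and -0.312 with GC content, a relation across genes, which are not independent replicates. The 223 of these whose longest transcript had at most 1000 bases had a median of 0.25, near that of the ribosomal list. The 2597 with at least 6000 bases had a median of -0.0073. Ribosomal protein genes were not left out of these sets.

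Other called lists were heat shock at 0.23, glycolysis at 0.17 with 4 adjusted over the list alone, hypoxia at 0.18 with SLC2A3 called and 4 higher and 1 lower adjusted over the list alone, stellate and fibroblast at 0.16, mitochondrially encoded mRNA at 0.16 and ER stress at 0.053, with 0 members of heat shock and the last 3 lists called over all genes or adjusted over the list alone. None held, from adjusted p = 0.421 with an estimated correlation for heat shock to 0.541 for hypoxia. The camera adjusted p of these lists were 1.86e-05, 2.80e-05, 0.000214, 0.000624, 0.000624 and 0.0457 in that order. Called medians moved by over 1.5 times without MCF-10A EV replicate 1 for stellate and fibroblast genes (0.25), without MCF-10A EV replicate 2 for glycolysis genes (0.30) and ER stress genes (0.089), and without MDA-MB-231 EV replicate 1 for heat shock genes (0.13). Hypoxia stood at 0.083 without MCF-10A EV replicate 1 and mitochondrially encoded mRNA at 0.10 without MDA-MB-231 EV replicate 2, both without a call. The mitochondrial list was at 0.038 after the length and GC correction, also without a call. ER stress lost its call at 0.053 without MCF-10A EV replicate 1, and at 0.095 and 0.069 without MDA-MB-231 EV replicates 1 and 2. Not called were alpha cells at 0.059 (camera adjusted p = 0.214), pyruvate and TCA cycle at 0.039 (0.148), immediate early genes at 0.068 (0.350), miR-122 targets at 0.047 (0.278), TGF-beta response at 0.053 (0.223) and basal epithelial genes at -0.054 (0.758). Median and test differed in sign for leukocyte genes (LYZ called and 1 adjusted over the list alone, median 0.099, mean -0.016, camera adjusted p = 0.986), Schwann cells (0.17, test downward, 0.997), dedifferentiation (CD44 called, 2 higher and 2 lower adjusted over the list alone, 0.065, test downward, 0.986) and interferon-stimulated genes (-0.018, test upward, 0.986). The same held for cell cycle (median -0.055, test upward, camera adjusted p = 0.829), p53 and apoptosis (-0.038, test upward, 0.997) and cholesterol biosynthesis (-0.0088, mean 0.019, 0.758). In the other lists not called here, 0 members were called over all genes or adjusted over the list alone. ALAS2 of the blood list was at 1.37 ± 0.85.

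At an unadjusted p under 0.05 there were 2190 genes, and the replicates of the 2 groups did not overlap for 44.5% of genes, where chance gives 33.3%. The number of calls hung on single libraries. It was 24 without MCF-10A EV replicate 2, with 18 of the 102 genes among them, 44 without MDA-MB-231 EV replicate 2, with 29 of the 102, and 396 and 383 without PBS replicates 1 and 2, with 101 of the 102 each time.

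**Figure D1:**
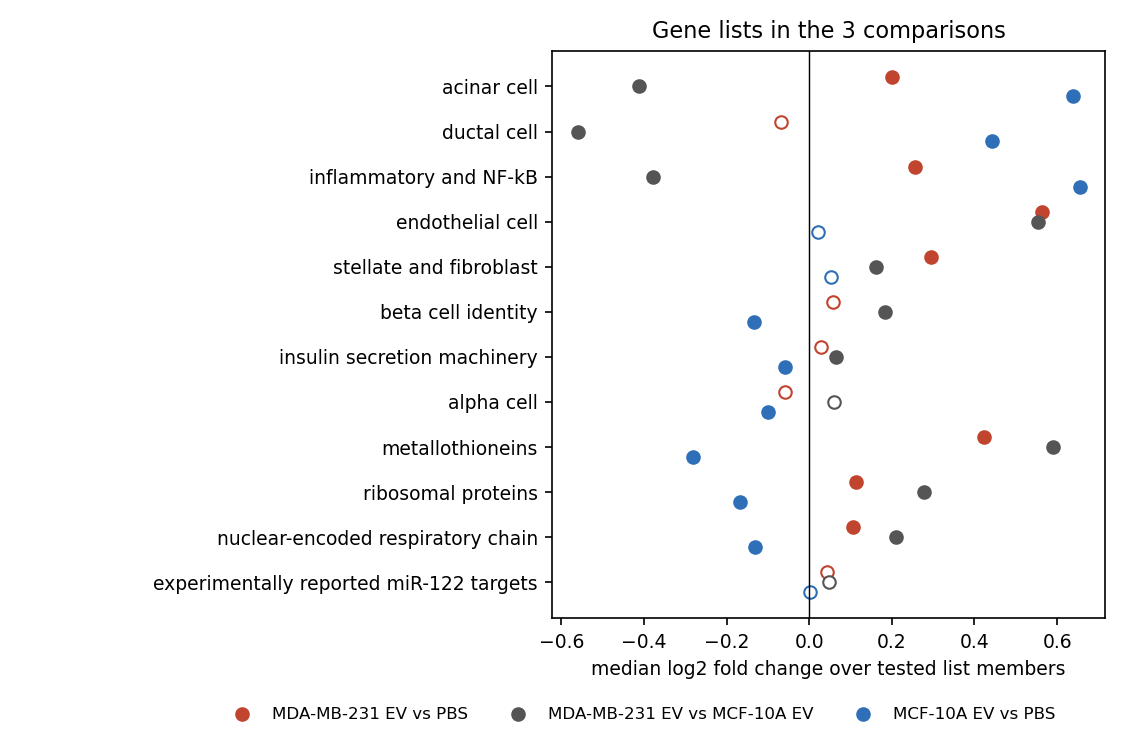
Median log2 fold change over the tested members of 12 gene lists in the 3 comparisons (red, MDA-MB-231 EV vs PBS; grey, MDA-MB-231 EV vs MCF-10A EV; blue, MCF-10A EV vs PBS), filled where camera with the preset correlation called the list. Ductal genes stood at 0.44 in MCF-10A EV vs PBS and at -0.56 in MDA-MB-231 EV vs MCF-10A EV, and no list held with an estimated correlation.

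The comparison of MCF-10A EV with PBS sets islets given vesicles of a non-tumorigenic line beside islets given PBS. Called higher with MCF-10A EV were 5 of 27 acinar, 3 of 17 ductal and 2 of 32 inflammatory genes. The shifts of these lists did not hold with an estimated correlation (adjusted p = 0.378 with an estimated correlation for each). REG1A, which encodes a secreted acinar protein, stood at 2071 ± 187 CPM against 1258 ± 98.6 (log2 fold change 0.72 ± 0.11), and CTRB1 at 90.2 ± 4.27 against 53.3 ± 5.80 (0.76 ± 0.11). In the ductal list SLC4A4 was at 0.66 ± 0.094 and ONECUT2 at 0.61 ± 0.11. Among inflammatory genes CXCL2 was at 23.4 ± 1.19 against 10.6 ± 0.191 (1.13 ± 0.18) and LCN2, an iron-siderophore binding protein of the acute response, at 0.65 ± 0.11. LYZ rose with a log2 fold change of 0.92 ± 0.10. The adjusted p was 0.00312 for REG1A, 0.00229 for CTRB1, 0.00204 for SLC4A4, 0.0117 for ONECUT2, 0.00401 for CXCL2, 0.00630 for LCN2 and 0.000329 for LYZ by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Calls were lost without MCF-10A EV replicate 2 for REG1A (0.63), SLC4A4 (0.56), ONECUT2 (0.58) and LCN2 (0.62).

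There were 100 called genes, 99 higher and 1 lower. With the same limit of a mean CPM of at least 5, the 10 largest rises were CA12, a membrane carbonic anhydrase (log2 fold change 1.40 ± 0.21), the intestinal transcription factor CDX2 (1.34 ± 0.29), GPC4 (1.33), AKR1B10 (1.15 ± 0.15), CXCL2, CEACAM7 (61.3 ± 3.77 against 27.9 ± 5.04 CPM, 1.13 ± 0.13), albumin, ALB (1.11 ± 0.16), PNLIPRP1 (1.08 ± 0.16), UGT2B15 (1.06) and PIGR, which carries immunoglobulins across epithelia (1.03 ± 0.13). The adjusted p ran from 0.000329 for CEACAM7 to 0.0436 for CDX2 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. SERPINB2, a plasminogen activator inhibitor, was the gene that fell (-1.54 ± 0.26, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00752). THAP1 (-0.84 ± 0.20), B3GALNT1 (-0.54 ± 0.14), PCDHA5 (-0.93 ± 0.24) and the pseudogene PKD1P5 had the next smallest p among lower genes and were not past the threshold, with an adjusted p of 0.0611 for PKD1P5 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. CA12 lies on chromosome 15, 63321378 to 63382161 (hg38) and SERPINB2 on chromosome 18, 63871692 to 63903890. Of the 21 called genes the rule named, 8 stayed called without each of the 6 libraries, namely AKR1B10, CXCL2, CEACAM7, UGT2B15, CTRB1, REG1B, LYZ and GDF15. The calls of the others were lost without PBS replicate 1 for CA12 (1.27), CDX2 (1.23), GPC4 (0.98), ALB (0.94), PNLIPRP1 (1.16), PIGR (1.09) and SERPINB2 (-1.09), without PBS replicate 2 for CA12 (1.54), ALB (1.29) and PIGR (0.97), without MCF-10A EV replicate 1 for GPC4 (1.30), and without MCF-10A EV replicate 2 for CDX2 (1.02) and GPC4 (1.35). The threshold was passed without PBS replicate 2 by B3GALNT1 (-0.66) and PCDHA5 (-1.15), and without MDA-MB-231 EV replicate 2 by THAP1 (-0.84), and by PKD1P5 without either MDA-MB-231 EV replicate.

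Acinar genes had a median of 0.64, with 24 of 27 positive, 5 called over all genes and 11 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.24e-23, and adjusted p = 0.378 with an estimated correlation). Ductal genes had a median of 0.44, with 17 of 17 positive, 3 called and 10 adjusted over the list alone (camera adjusted p = 1.57e-19, and adjusted p = 0.378 with an estimated correlation). Inflammatory genes had a median of 0.65, with 31 of 32 positive, CXCL2 and LCN2 called and 11 adjusted over the list alone (camera adjusted p = 3.46e-33, and adjusted p = 0.378 with an estimated correlation). REG1B was at 0.85 ± 0.12 and ANXA4 at 0.55 ± 0.11, both called, while PRSS1 (0.65 ± 0.17), KRT19 (0.27 ± 0.13), NFKBIA (0.93 ± 0.20) and the complement gene CFB (1.26 ± 0.24) were not past the threshold. These 3 lists stayed called without each of the 6 libraries, with medians from 0.56 to 0.80 for acinar, 0.38 to 0.50 for ductal and 0.58 to 0.81 for inflammatory genes. Of the 100 called genes, 8 were members of the duct or acinar lists. PRSS1 passed the threshold without either MDA-MB-231 EV replicate (0.65 each time), and the call of ANXA4 was lost without MCF-10A EV replicate 1 (0.57) and 2 (0.54).

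Medians of the endocrine lists were negative. Beta cell identity had a median of -0.13 with 22 of 24 negative (camera, Benjamini-Hochberg adjusted p = 0.000171, and adjusted p = 0.411 with an estimated correlation). Delta, PP and epsilon cell genes stood at -0.18 (camera adjusted p = 0.0104, and adjusted p = 0.378 with an estimated correlation). Alpha cell genes stood at -0.10 (camera adjusted p = 0.0248, and adjusted p = 0.867 with an estimated correlation) and insulin secretion machinery at -0.059 (camera adjusted p = 0.0446, and adjusted p = 0.867 with an estimated correlation). Of these 4 lists 0 members were called over all genes or adjusted over the list alone. INS was at 6281 ± 913 CPM against 8655 ± 2377 (log2 fold change -0.46 ± 0.16), GCG at -0.28 ± 0.13, IAPP at -0.35 ± 0.39, SST at -0.084 ± 0.12, PPY at -0.39 ± 0.74, SLC2A2 at -0.059 ± 0.14, PDX1 at -0.0064 ± 0.092 and MAFA at -0.033 ± 0.10, none past the threshold. PKM was at 0.046 ± 0.11, with -0.060 after the length and GC correction, CS at 0.097 ± 0.089 and COL1A1 at 0.32 ± 0.35. Without PBS replicate 2 INS (-0.72) and COL1A1 (0.86) passed the threshold, INS with an adjusted p of 0.00102 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Beta cell identity stood at -0.037 without PBS replicate 1 and was no longer called. Alpha cell genes stood at -0.047 without PBS replicate 2 and at 0.036 without MCF-10A EV replicate 2, and insulin secretion machinery at 0.012 without PBS replicate 2 and -0.018 without MCF-10A EV replicate 2. None of these was called. The latter also lost its call without either MDA-MB-231 EV replicate, at -0.059 and -0.059. Called medians moved by over 1.5 times without PBS replicate 2 for beta cell identity genes (-0.23), and without MCF-10A EV replicate 1 for insulin secretion genes (-0.089), alpha cell genes (-0.22) and delta, PP and epsilon cell genes (-0.12).

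Ribosomal proteins had a median of -0.17 with 75 of 78 negative (camera, Benjamini-Hochberg adjusted p = 3.73e-12, and adjusted p = 0.867 with an estimated correlation). The respiratory chain stood at -0.13 (camera adjusted p = 3.71e-06, and adjusted p = 0.867 with an estimated correlation), mitochondrially encoded mRNA at -0.21 (camera adjusted p = 1.87e-05, and adjusted p = 0.789 with an estimated correlation) and metallothioneins at -0.28 (camera adjusted p = 0.0371, and adjusted p = 0.867 with an estimated correlation). Their members were not past the threshold over all genes or adjusted over the list alone. RPL11 was at -0.31 ± 0.094, COX7A2 at -0.34 ± 0.11, MT-ATP8 at -0.26 ± 0.090 and MT1E at -0.39 ± 0.17. Without PBS replicate 1 the ribosomal and the respiratory chain medians were -0.021 and -0.019 and not called. The respiratory chain stood at -0.073 without MCF-10A EV replicate 2 and metallothioneins at -0.090 without MCF-10A EV replicate 1, again not called. After the length and GC correction metallothioneins were at -0.29, also not called. Still called, they moved by over 1.5 times without PBS replicate 1 for mitochondrially encoded genes (-0.072), without PBS replicate 2 for ribosomal protein genes (-0.30), respiratory chain genes (-0.26) and mitochondrially encoded genes (-0.35), and without MCF-10A EV replicate 2 for metallothionein genes (-0.66). Log2 fold changes across protein-coding genes with a mean CPM of at least 5 had a Spearman rho of 0.390 with GC content and 0.0370 with transcript length, and genes are not independent replicates. The 218 of these whose longest transcript had at most 1000 bases had a median of -0.12.

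Leukocyte genes had a median of 0.15, with LYZ called and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0248, and adjusted p = 0.382 with an estimated correlation). Dedifferentiation genes had a median of 0.13, with CD44 (0.52 ± 0.097) called and 1 adjusted over the list alone (camera adjusted p = 0.0260, and adjusted p = 0.867 with an estimated correlation). Immediate early genes had a median of 0.11, with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0472, and adjusted p = 0.867 with an estimated correlation). These calls were lost for leukocyte genes without PBS replicate 2 (0.17) and MCF-10A EV replicate 1 (0.19), and for dedifferentiation without PBS replicate 1 (-0.0079) and MCF-10A EV replicate 2 (0.0028). Immediate early genes lost theirs without PBS replicate 1 (-0.018), MCF-10A EV replicate 1 (0.12) and 2 (0.12) and MDA-MB-231 EV replicate 2 (0.11), and after the length and GC correction (0.051). Called medians moved by over 1.5 times without PBS replicate 1 for leukocyte genes (0.046), without PBS replicate 2 for immediate early genes (0.28) and dedifferentiation genes (0.32), without MCF-10A EV replicate 1 for dedifferentiation genes (0.21), and without MCF-10A EV replicate 2 for leukocyte genes (0.079). The call of CD44 was lost without MCF-10A EV replicate 2 (0.48). Not called were endothelial genes at 0.020 (camera adjusted p = 0.542), with ENG at 0.43 ± 0.16, Schwann cells at -0.039 (0.779) and basal epithelial genes at -0.018 (0.719). Metabolic and stress lists were not called either, with glycolysis at -0.052 (camera adjusted p = 0.311), pyruvate and TCA cycle at -0.064 (0.296), ER stress at -0.015 (0.715) and heat shock at -0.066 (0.287). Hypoxia was at 0.013 (camera adjusted p = 0.542), with CA12 called and 2 adjusted over the list alone, interferon-stimulated genes at 0.088 (0.544), cell cycle at 0.17 (0.568) and TGF-beta response at 0.074 (0.419), with 1 higher and 1 lower adjusted over the list alone. Signs differed for stellate and fibroblast genes (median 0.052, mean -0.021, camera adjusted p = 0.767) and for p53 and apoptosis (median -0.012, mean 0.098, 0.311), where GDF15, a stress cytokine, was called (0.68 ± 0.11) and 1 adjusted over the list alone. Cholesterol biosynthesis (median 0.0063, camera adjusted p = 0.828) and miR-122 targets (median 0.00099, camera adjusted p = 0.943) had a positive median with a downward test, and ALAS2 of the blood list was at -0.48 ± 0.88. In the lists not called, apart from hypoxia, TGF-beta response and p53 and apoptosis, 0 members were called over all genes or adjusted over the list alone.

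At an unadjusted p under 0.05 there were 1640 genes, and the replicates of the 2 groups did not overlap for 38.1% of genes, where chance gives 33.3%. Calls numbered 420 without PBS replicate 2, with 87 of the 100 genes among them, 47 without PBS replicate 1, with 39 of the 100, and 24 without MCF-10A EV replicate 2, all 24 among the 100. They numbered 171 and 176 without MDA-MB-231 EV replicates 1 and 2, with all 100 among them each time.

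**Figure D2:**
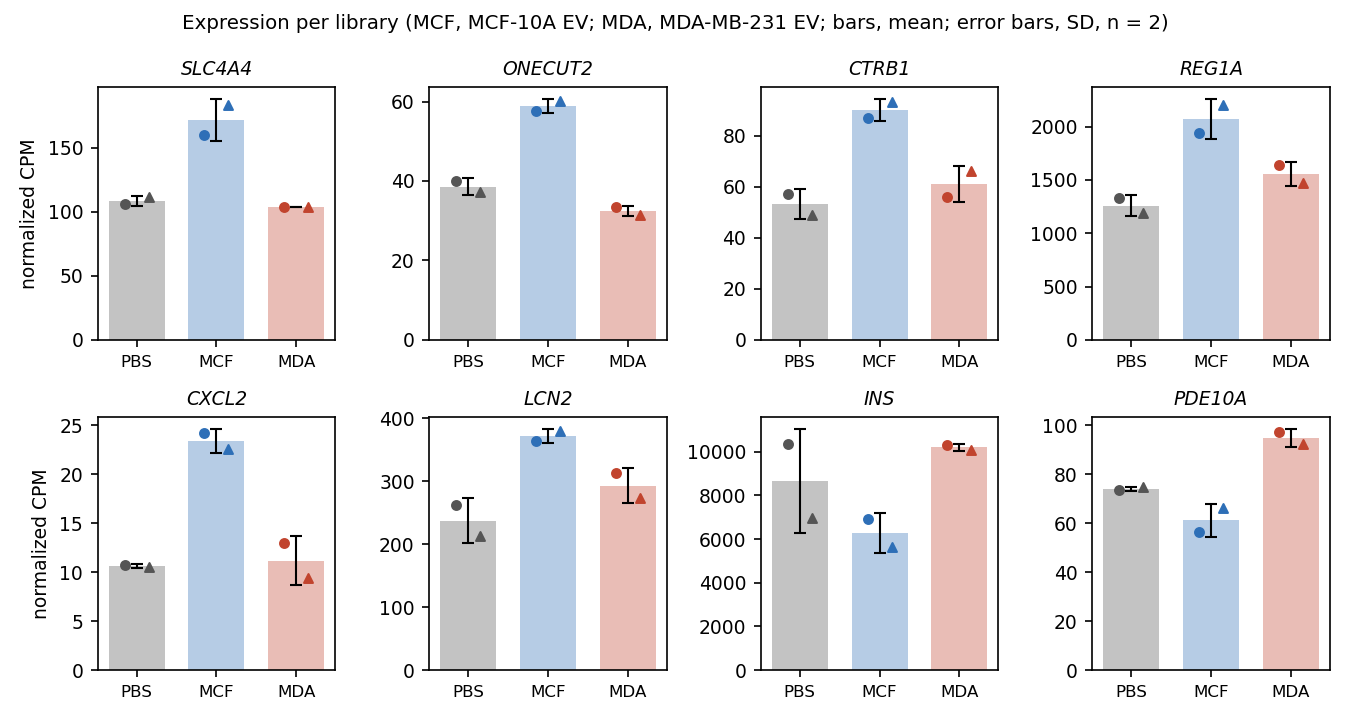
TMM-normalized CPM of 8 genes in the PBS, MCF-10A EV and MDA-MB-231 EV libraries (circles, replicate 1; triangles, replicate 2; bars, mean; error bars, SD, n = 2). Both MCF-10A EV libraries lay above the other 4 for SLC4A4, ONECUT2, CTRB1, REG1A, CXCL2 and LCN2, with group means for SLC4A4 of 172, 109 and 104 in MCF-10A EV, PBS and MDA-MB-231 EV.

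**Figure D3:**
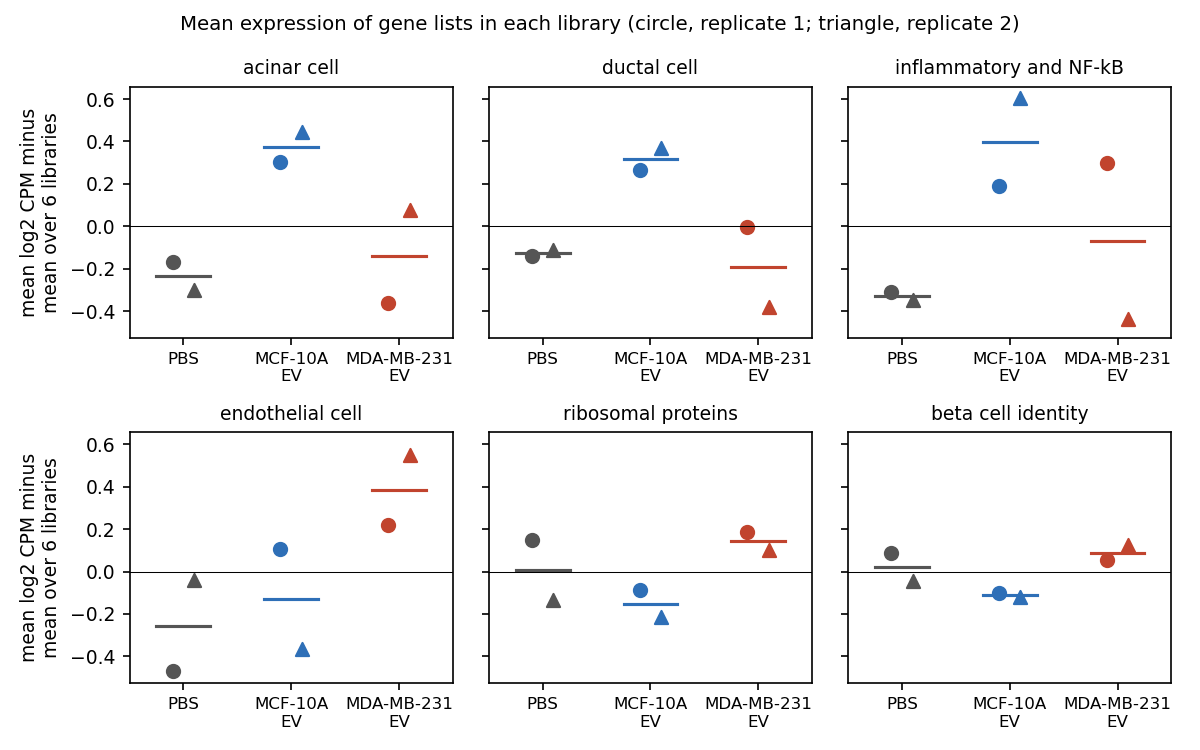
Mean log2 CPM of 6 gene lists in each library, relative to the mean over the 6 libraries (circles, replicate 1; triangles, replicate 2; lines, group means). The MDA-MB-231 EV replicates lay apart for inflammatory genes, replicate 2 minus replicate 1 being -0.74, for acinar genes (0.44) and for ductal genes (-0.38).

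The differences of the 2 EV groups from PBS, called EV responses for short without a test of their cause, were also set side by side. Across the 19696 genes, which are not independent replicates, log2 fold changes of MDA-MB-231 EV and of MCF-10A EV against PBS had a Pearson r of 0.459 and a Spearman rho of 0.360, but both share the PBS libraries, and 50 simulations with no effect gave a mean r of 0.491. The covariance was 0.0703 against 0.0587 in the simulations, a difference of 0.0116. With 2 PBS libraries the controls could not be split into sets of 2, so part of any excess may come from the shared controls. No gene was called in the same direction in both, since edgeR quasi-likelihood called 0 against PBS with MDA-MB-231 EV, where 923 had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 0. With genes of a mean CPM of at least 5 the r was 0.299.

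Of the 94 genes lower with MDA-MB-231 EV than with MCF-10A EV and the 99 higher with MCF-10A EV than with PBS, 51 were shared, SLC4A4, ONECUT2, CTRB1, CXCL2, LYZ and CD44 among them. Independent lists would share 0.472 genes, but both comparisons use the MCF-10A EV libraries, so part of the overlap comes from those libraries. For the 51 shared genes the median log2 fold change was 0.77 in MCF-10A EV against PBS and -0.83 in MDA-MB-231 EV against MCF-10A EV. In MDA-MB-231 EV against PBS, 24 of the 51 were positive.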

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

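The medians of the gene lists had been seen before any test in this part was chosen, and the comparison of exocrine with other non-endocrine lists, the spread of acinar and ductal genes, the limit of the inflammatory test to groups in which duct and acinar genes moved the same way, and the correction for length and GC content, as well as the draws with uncertain standard errors for the endothelial genes, were chosen only after the result itself was seen. Of the 5 lists called in all 3 comparisons by camera (Benjamini-Hochberg adjusted), 3 had opposite directions against PBS with the 2 kinds of EV, and the difference itself was called. Respiratory chain genes differed by a median of 0.21 between MDA-MB-231 EV and MCF-10A EV, at 0.11 and -0.13 against PBS (adjusted p = 7.96e-15, and adjusted p = 0.466 with an estimated correlation). Ribosomal protein genes differed by 0.28, at 0.11 and -0.17 against PBS (camera adjusted p = 7.79e-33, and adjusted p = 0.427 with an estimated correlation). Metallothioneins differed by 0.59, at 0.42 and -0.28 against PBS (camera adjusted p = 3.04e-07, and adjusted p = 0.353 with an estimated correlation). The opposite signs of 2 of these lists hung on PBS replicate 2, since without it the ribosomal median was -0.017 with MDA-MB-231 EV and -0.30 with MCF-10A EV, and the respiratory chain median -0.016 and -0.26. Calls against PBS with MCF-10A EV were lost without PBS replicate 1, at -0.021 for ribosomal and -0.019 for respiratory chain genes, and for the latter without MCF-10A EV replicate 2, at -0.073. Metallothionein medians kept opposite signs without each library, from 0.20 to 0.45 with MDA-MB-231 EV and from -0.66 to -0.090 with MCF-10A EV against PBS. The fall with MCF-10A EV lay mostly in replicate 1. Relative to the mean over the 6 libraries, the metallothionein mean (log2 CPM) was -0.56 and -0.012 in MCF-10A EV replicates 1 and 2. In PBS replicates 1 and 2 it was -0.10 and -0.052, so MCF-10A EV replicate 2 lay above both. Metallothionein calls were lost without PBS replicate 2, at 0.45 with MDA-MB-231 EV, and without MCF-10A EV replicate 1, at -0.090 with MCF-10A EV.

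Of 44 duct and acinar genes, 8 were called higher in the MCF-10A EV than in the PBS libraries, and the shift of both lists was lost with an estimated correlation (adjusted p = 0.378 with an estimated correlation for each). A lower share of endocrine cells would raise all other cell types alike, but duct and acinar members exceeded stellate and endothelial members by a median of 0.55 (95% bootstrap interval over genes 0.44 to 0.69, medians 0.60 and 0.052 over 44 and 34 genes). Without PBS replicate 2 the excess was 0.24, outside that interval, which covers the spread over genes and not that between libraries. Duct and acinar genes then had a median of 0.50, and stellate and endothelial genes one of 0.26. Without PBS replicate 1 the excess was 0.68. The endothelial mean differed by 0.43 between the PBS replicates and by -0.47 between the MCF-10A EV replicates (replicate 2 minus replicate 1). In these libraries the excess argues against a lower endocrine share as the whole cause, but its size hung on the PBS library used. The rise of stellate and endothelial genes without PBS replicate 2 leaves such a share open as a part. More exocrine tissue in those wells cannot be told apart from a response to the vesicles, which was not tested, since the 93.2% of positive members (41 of 44) restate the pattern, and while the spread of the acinar genes argues against a single factor for all of them (heterogeneity Q of 56.5, n = 27 genes, p = 0.00585 over 100000 draws), acinar genes also made by other cells would rise less, and a single factor for the 17 ductal genes stays open (Q of 28.1, p = 0.0784). Inflammatory genes passed the bound of 0.3 set beforehand against following exocrine tissue, as they differed by 0.74 between the MDA-MB-231 EV replicates, opposite to the duct and acinar mean and 0.36 beyond the ductal genes, but that mean joins opposite moves (-0.38 ductal, 0.44 acinar) and 1 pair of libraries leaves this open. In the MCF-10A EV pair, the one in which duct and acinar genes moved the same way, they differed by 0.41, which is 0.29 beyond that mean and 0.31 beyond the ductal genes, on either side of the bound.

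Ribosomal protein genes had a positive median with MDA-MB-231 EV against MCF-10A EV, with 0 of 78 called over all genes by edgeR quasi-likelihood and an adjusted p = 0.427 with an estimated correlation. The median was 0.28 with TMM, 0.28 with median-of-ratios factors and 0.22 with library totals, so the choice among these scalings is not the cause. TMM factors ran only from 0.975 to 1.03. These scalings were therefore too alike to test an error of scaling that they share. After a correction for transcript length and GC content the ribosomal median was 0.30, while the median of all genes moved from -0.0038 to 0.063. The list stayed called with the preset correlation. Lengths and GC content were those of each gene's longest annotated transcript, with a median of 1841.5 bases for ribosomal protein genes. The shorter transcripts a gene may express were not corrected for, so the correction cannot decide whether such a trend is the whole cause. The ribosomal median was not lowered, but the median of all genes rose by more, so the ribosomal shift relative to all genes became smaller. Whether the correction removed the trend at these genes was not tested. As a part of the cause the trend cannot be told apart from other causes either. Genes matched on these lengths, GC content and expression shifted by 0.13 on average (highest of 10000 draws 0.21). This left 54.2% of the median, between the bounds of 25% and 75% set for a decision before the draws were made. A response to the vesicles may account for the rest but was not tested.

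Endothelial genes had a positive median with MDA-MB-231 EV against PBS, with 0 of 14 called over all genes by edgeR quasi-likelihood and an adjusted p = 0.557 with an estimated correlation. More endothelial cells would raise all members by about one factor, and 13 of 14 were positive around a weighted mean of 0.45. Their spread gave a heterogeneity Q of 28.5 (n = 14 genes, p = 0.00764 by the chi-square distribution with 13 degrees of freedom), but p = 0.027 over 100000 draws in which the standard errors varied as 19.4 degrees of freedom allow. The chi-square p lies under the bound of 0.01 set beforehand against one factor for all members. The p of the draws, which were chosen after that result, lies between the bounds of 0.01 and 0.05. The verdict thus hung on the choice of test, and more endothelial cells and a response of these cells cannot be told apart. A single library did not carry the whole difference, but single libraries carried much of it. The median was 0.36 without PBS replicate 1 and 0.32, or 56.2% of its value, without MDA-MB-231 EV replicate 2.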

How the results depend on the processing

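The length and GC correction was chosen after the data were seen, and the other alternatives were not. All 102 and 100 calls between MDA-MB-231 EV and MCF-10A EV and between MCF-10A EV and PBS kept their sign under each alternative in which they were tested. Median-of-ratios scaling gave 0, 102 and 93 calls in MDA-MB-231 EV vs PBS, MDA-MB-231 EV vs MCF-10A EV and MCF-10A EV vs PBS. In that order there were 30, 429 and 294 calls with no filter on low counts and 3, 281 and 155 with only the 4 samples compared. DESeq2 gave 5 against 0 for MDA-MB-231 EV vs PBS by edgeR quasi-likelihood, where 923 genes had an unadjusted p under 0.05 and limma-voom called 0. The length and GC correction gave 166 calls in MDA-MB-231 EV vs MCF-10A EV, 56.0% of them higher against 7.84%, with 72 of the 102 among them. It gave 67 calls in MCF-10A EV vs PBS, with 59 of the 100 among them, and 0 in MDA-MB-231 EV vs PBS. In the first 2 of these comparisons it also moved the median log2 fold change of all genes, to 0.063 and -0.059. Without each library in turn there were 0 to 42, 24 to 396 and 24 to 420 calls. Of the 14, 16 and 14 lists called by camera, 0 held in each comparison with an estimated correlation and 0 with fry. The cause was not tested, except that leaving out samples or filters changes the genes and degrees of freedom by construction.

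The replicate numbers shared between groups did not pair the samples, as deviations of same-numbered samples correlated at 0.030, -0.0020 and -0.038. With the replicate block there were 0, 78 and 65 calls, and 69 of the 102 and 61 of the 100 were among them. The ER stress list in MDA-MB-231 EV vs MCF-10A EV lost its call with it, at 0.053.

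After the length and GC correction, CS in MDA-MB-231 EV vs MCF-10A EV was at 0.0012, COL1A1 at 0.23 and PKM in MCF-10A EV vs PBS at -0.060. The medians of all genes were then 0.063 and -0.059 in these comparisons. The relation of the EV responses gave r = 0.299 with mean CPM of at least 5 and 0.386 to 0.676 without each library, with no value for unchanged groups simulated under these settings. The sample similarity, mean correlation within minus between groups, was 0.00134 over all genes and 0.0351 over the 500 most variable.

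Signs changed without a single library, and the cause was not tested. In MDA-MB-231 EV vs PBS medians ran from -0.054 to 0.34 for acinar cell, -0.016 to 0.22 for respiratory chain, -0.017 to 0.25 for ribosomal proteins, -0.080 to 0.62 for inflammatory and -0.14 to 0.52 for TGF-beta response genes. In MCF-10A EV vs PBS the ranges were -0.22 to 0.036 for alpha cell, -0.089 to 0.012 for insulin secretion, -0.018 to 0.28 for immediate early and -0.0079 to 0.32 for dedifferentiation genes. Single genes in MDA-MB-231 EV vs PBS ran from -0.019 to 0.55 for INS, -0.27 to 0.55 for IAPP, -0.0046 to 0.16 for PDX1, -0.077 to 0.24 for MAFA, -0.035 to 0.026 for GCG, -0.053 to 0.25 for PKM, -0.0060 to 0.070 for CS, -0.078 to 0.39 for PRSS1 and -0.079 to 0.85 for COL1A1. In MDA-MB-231 EV vs MCF-10A EV MAFA ran from -0.044 to 0.28 and COL1A1 from -0.092 to 0.083. In MCF-10A EV vs PBS the ranges were -0.64 to 0.012 for IAPP, -0.058 to 0.045 for PDX1, -0.084 to 0.016 for MAFA, -0.23 to 0.076 for SST, -1.31 to 0.18 for PPY, -0.25 to 0.16 for SLC2A2, -0.10 to 0.21 for PKM and -0.076 to 0.86 for COL1A1. Genes not called that kept their sign but moved by over 1.5 times ran, in MDA-MB-231 EV vs PBS, from 0.78 to 1.49 for FLT1, 0.72 to 1.67 for IL1B, -1.31 to -0.52 for SERPINB2, 0.027 to 0.34 for SST, 0.097 to 1.20 for PPY, 0.0088 to 0.41 for SLC2A2 and -0.40 to -0.0066 for KRT19. In MDA-MB-231 EV vs MCF-10A EV they ran from 0.075 to 0.89 for IAPP, 0.0017 to 0.16 for PDX1, 0.16 to 0.40 for GCG, 0.49 to 2.06 for PPY, 0.0030 to 0.097 for PKM, -0.10 to -0.027 for CS, -0.72 to -0.26 for PRSS1 and -0.67 to -0.28 for KRT19, and in MCF-10A EV vs PBS from -0.72 to -0.15 for INS, -0.40 to -0.16 for GCG and 0.10 to 0.46 for KRT19. Of the called lists, 1 of 14, 10 of 16 and 5 of 14 stayed called without each library. Depth was similar in the 6 libraries, and the 2 replicates per group limit these results.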

Other observations

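All genes in this part were chosen after their values were seen, and no list of them was tested. Whether the call of each held without single libraries is not given here. Between MCF-10A EV and PBS, DUOX2, a peroxide-producing oxidase of mucosal surfaces, had a log2 fold change of 0.99 ± 0.15, and the membrane mucin MUC3A 0.76 ± 0.12, with adjusted p of 0.0117 and 0.00353 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Both were lower with MDA-MB-231 EV than with MCF-10A EV, at -0.90 ± 0.15 and -1.04 ± 0.12 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0210 and 0.000688). MUC16 and MUC5B were called between the 2 kinds of EV, at -2.38 ± 0.39 and -1.06 ± 0.21, and not between MCF-10A EV and PBS, at 0.51 ± 0.33 and 0.29 ± 0.20, a difference between comparisons that was not tested. The receptor genes ERBB2, ERBB3 and FGFR3 stood at 0.76 ± 0.14, 0.63 ± 0.11 and 0.79 ± 0.17 with MCF-10A EV against PBS, and at -0.72 ± 0.14, -0.59 ± 0.11 and -1.01 ± 0.17 with MDA-MB-231 EV against MCF-10A EV, all called.

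C1R and C1S, proteases of the classical complement pathway, rose with MCF-10A EV against PBS by log2 fold changes of 0.84 ± 0.14 and 0.65 ± 0.12, their inhibitor SERPING1 by 0.61 ± 0.13, and CRP by 0.99 ± 0.13, with adjusted p from 0.00369 for CRP to 0.0487 for SERPING1 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. CD74, the invariant chain of antigen presentation, rose by 0.65 ± 0.12, the growth factor gene CSF1 by 0.95 ± 0.16 and CX3CL1 by 0.99 ± 0.20. With MDA-MB-231 EV against PBS, C1R stood at 0.36 ± 0.14, C1S at 0.21 ± 0.12, SERPING1 at -0.15 ± 0.13 and CRP at 0.46 ± 0.13, none past the threshold, each with an adjusted p of 0.998 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. The largest rise among the called genes was that of CPXM1, at 2.44 ± 0.37, and it was lower with MDA-MB-231 EV than with MCF-10A EV, at -2.31 ± 0.37. Despite the size of their changes, CPXM1 and MUC16 were not taken by the rule, which asked for a mean CPM of at least 5 and replicates apart.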
